A study of Sus scrofa with 4 samples.

How the data were processed

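The series holds 4 SAGE libraries from total RNA of Longissimus dorsi biopsies, 1 for each combination of animal (a Landrace x Duroc castrate, called Dunel in the labels, and a Large White castrate) and age (3 and 9 months). Groups were taken from the sample titles. A separate age field gives 3 months for every sample, which disagrees with the titles of the 9 month samples, and the titles were followed. Per the labels, the RNA was isolated with TRIZOL. The biopsies at both ages were taken from the same pig of each line, per the series' design text.

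Per the file headers, the authors obtained the tag counts with SAGEparser.pl version 3.1, which splits sequenced concatemers at the anchoring site CATG into ditags and takes a 17-base tag from each end. Per the file headers, ditags of 32 to 36 bases were kept, ditags with ambiguous bases or linker sequence were dropped, and repeated ditags were not removed. The deposited percent values are each tag's count over the library's valid tags. Counts were used as deposited, and the percent column served only to check them. An aligner, a genome build and a gene assignment are not given in the sources used here. The libraries came from 637, 549, 654 and 552 clones (Landrace x Duroc at 3 and 9 months, Large White at 3 and 9 months), with 6795, 6490, 6565 and 6710 valid ditags. Between 63.3% and 69.2% of the unique ditags were shorter than 34 bases, so that their tags share 1 or 2 bases and the last positions of a tag are less certain than the others. The deposited lists of repeated ditags were used to count each ditag a single time as an alternative.

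The tests had been planned on genes, with tags assigned through transcripts. No transcript sequences were used here, so every feature is a tag, no gene is named, and the 22 gene lists that had been fixed were not run. Tags with 10 or more copies over the 4 libraries were tested, which left 464 tags that hold 53.5% of all tags. The age change over both pigs was fitted with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, TMM library sizes, pig as a block). This fit has 1 residual degree of freedom. Each pair of libraries was compared with a two-sided Fisher's exact test per tag on its count against the rest of the library. The difference of the age changes was tested with a z test on log odds ratios with 0.5 added to each count. Benjamini-Hochberg adjusted p-values under 0.05 passed in every test. Log2 changes have 0.5 added to each count, and fold intervals are at 95%. Shares have Wilson intervals at 95%, and the limit for a count of 0 is 3 counts of the library's total. Ditags were amplified without molecular identifiers, so tags are not independent molecules. Python 3.11.15, SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3, edlib 1.3.9.post1 and matplotlib 3.10.9 were used.

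Tags are named by a rule: the 3 with the smallest p in each direction of each comparison, among tags that passed or, for the age fit over both pigs, where none passed, among all tags tested. The rule, the tests and the alternatives were fixed before the data were examined, except where stated. The alternatives fixed in advance were a minimum of 5 or 20 tags, TMM or total-tag scaling, DESeq2 1.42.0, no pig block, each pig alone, the Audic-Claverie test, 1 added to each count, repeated ditags counted a single time, expected counts scaled within 5 classes of GC content, and leaving out tags 1 base away from a tag at least 50 times more abundant. Each GC class was scaled by its own TMM factor, so removing the GC trend also removes a shift of the whole library. Tags shortened to 15 bases, the age fit with repeated ditags counted a single time, the comparisons without the repeat-like family, and the overlaps and correlations between comparisons under TMM and GC scaling were added after seeing the data.

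The scripts were tested on simulated data drawn from the real tags' means and library sizes. For an age comparison within 1 pig, Fisher's test recovered 10 of 83 tags changed 2-fold and 34 of 84 changed 4-fold, and called 1 of 307 unchanged tags. For the test of the difference, 4 of 88 tags changed 2-fold and 11 of 93 changed 4-fold were recovered. The edgeR fit recovered 56 of 84 tags changed 4-fold where counting error was the only spread. It recovered 0 of 81 where the spread of the real libraries was added by a further draw from simulated counts, so that counting error entered again.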

Results

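Serial analysis of gene expression (SAGE), which counts short sequence tags taken next to a restriction site near the 3′ end of each transcript, was carried out on biopsies of the Longissimus dorsi muscle of castrated pigs. Per the series' design text, the 4 libraries came from 2 animals, a Landrace x Duroc pig (named Dunel in the labels) chosen as lean and a Large White pig chosen as fat on live weight and daily gain, each sampled at 3 and at 9 months of age. Each line was represented by 1 of the 10 pigs reared, so line and animal were the same variable, and each group held 1 library. The libraries held 13590 tags (Landrace x Duroc, 3 months), 12980 tags (Landrace x Duroc, 9 months), 13130 tags (Large White, 3 months) and 13420 tags (Large White, 9 months). Together they held 53120 tags of 17902 different sequences, of which 548 sequences were seen in all 4 libraries. A tag that was not seen in a library could have made up to 0.0221% to 0.0231% of it, the limit that a count of 0 allows. Intervals and limits cover counting error only. Tags are given by the 17 bases that follow CATG and were not matched to genes.

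The most frequent sequence in all libraries together was CTTTTCTCCACTCAAAG, with 1901 tags, followed by GAGGCCGTGGCCGCCCA with 1554 and TACCATCAATAAAGTAC with 1255. The 10 most frequent tags of each library made up 22.6% and 24.0% of the Landrace x Duroc libraries at 3 and 9 months. They made up 22.5% of the Large White library at 3 months and 12.6% at 9 months. The Large White 9 month library also held the most distinct tags, 7665 against 5158, 4437 and 5241 in the Landrace x Duroc 3 month, Landrace x Duroc 9 month and Large White 3 month libraries. Tags seen a single time made up 49.3% of it (95% Wilson interval 48.5% to 50.2%), against 29.5%, 25.8% and 32.5% of the other libraries in the same order. Mean GC content of the tags was 57.1% and 55.3% in the Landrace x Duroc libraries at 3 and 9 months, and 50.9% and 49.2% in the Large White libraries. Tags that held the polyadenylation signal AATAAA or ATTAAA made up 8.67% of the Large White 3 month library (8.20% to 9.16%). They made up 6.27% of the Large White 9 month library, and 5.25% and 5.72% of the Landrace x Duroc libraries at 3 and 9 months. The tag with 1255 copies named above holds this signal. By itself it made up 3.79% and 1.72% of the Large White libraries at 3 and 9 months. In the Landrace x Duroc libraries it made up 1.39% and 2.60%. The difference between the Large White shares therefore rests in part on this tag.

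**Figure D1:**
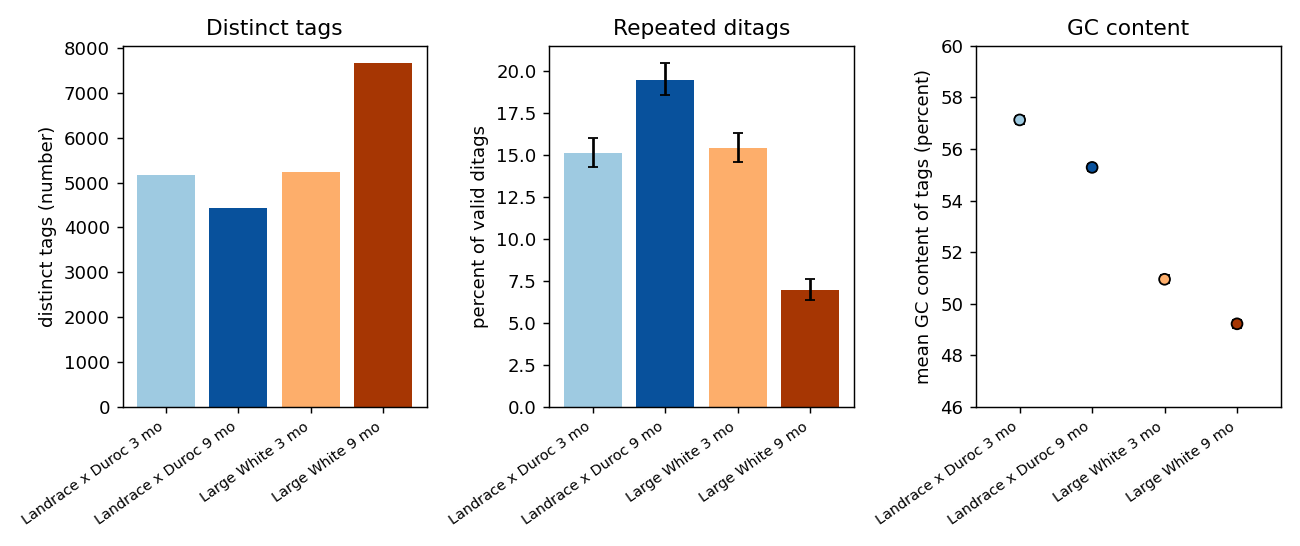
Distinct tags (number), repeated ditags (percent of valid ditags, with 95% Wilson intervals) and mean GC content of the tags (percent, with standard errors smaller than the points) in each of the 4 libraries; the GC axis does not start at 0. The Large White 9 month library stands apart with 7665 distinct tags and 6.94% repeated ditags, and the Large White libraries lie below the Landrace x Duroc libraries in GC content.

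The first comparison asked which transcripts changed between 3 and 9 months during growth of the lean Landrace x Duroc pig. ACTTCAACCCGGATGTG fell from 1.73% of tags to 0.262% (0.188% to 0.366%), a 6.52-fold decrease with a 95% interval of 4.56 to 9.31. TGCCCCTCCTCGCCAGG fell 6.42-fold, from 97 to 14 tags, and GCCAGAAGGTGGCTGAT fell 5.19-fold, from 100 to 18 tags. In the other direction, TGATGTCAAGGAAATAA rose 6.44-fold (3.83 to 10.8), from 16 to 101 tags, and ACCACTTACCGGAGCCC rose 4.78-fold (3.28 to 6.99), from 32 to 148 tags. TACCATCAATAAAGTAC, already frequent at 3 months, rose 1.87-fold from 189 to 338 tags. Two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 464 tags gave adjusted p-values between 4.93e-34 and 9.997e-11 for these 6 tags. In all, 50 of the 464 tags passed the threshold, 30 higher and 20 lower at 9 months. The tags that were lower had a median GC content of 67.6%, and those that were higher 44.1%, against 52.9% among all tags tested. Scaling the libraries by TMM turned the split to 24 higher and 29 lower, and counting each repeated ditag a single time left 31 tags, 20 higher and 11 lower, with TGATGTCAAGGAAATAA at a log2 change of 1.84 in place of 2.69.

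The same question was asked of the fat Large White pig. TAATACCAAGAATTGTT rose from 2 to 66 tags, a ratio of 26.0 with a counting interval of 7.36 to 92.0, and AATTAAAAAAAAAAAAA rose from 3 to 60 tags, a ratio of 16.9 (5.76 to 49.7). The latter holds only A and T and ends in a run of A, so it may not mark a single transcript. All tags that end in 8 A together went from 118 to 146, or from 0.899% to 1.09% of the library. AGGTTGCGGGTTCGGTC rose 7.63-fold (4.24 to 13.7), from 12 to 97 tags, and tags within 3 mismatches of it rose from 51 to 366 as a group. The abundant tags TACCATCAATAAAGTAC, CTTTTCTCCACTCAAAG and GAGGCCGTGGCCGCCCA fell, from 497 to 231, from 582 to 307 and from 387 to 197 tags, which were decreases of 2.20-fold, 1.94-fold and 2.01-fold. Adjusted p-values of these 6 tags by Fisher's exact test lay between 1.40e-22 and 7.89e-13. Of 464 tags, 48 passed the threshold, 12 higher and 36 lower at 9 months. The median log2 change over all tags tested was -0.50. TMM scaling brought that median to 0.03 and the log2 changes of the 3 abundant tags to -0.60, -0.42 and -0.47. Under TMM scaling 24 tags passed, 16 higher and 8 lower. With the GC trend removed 20 passed, 14 higher and 6 lower, and GAGGCCGTGGCCGCCCA, at a log2 change of -0.34, was no longer among them. Counting each repeated ditag a single time lowered the log2 change of TAATACCAAGAATTGTT from 4.70 to 3.29 and that of AATTAAAAAAAAAAAAA from 4.08 to 2.64. In 4 pairs of tags that differ by 1 base, the form of the Landrace x Duroc pig made up 1 of 67 tags of the Large White library at 3 months and 12 of 55 at 9 months.

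**Figure D2:**
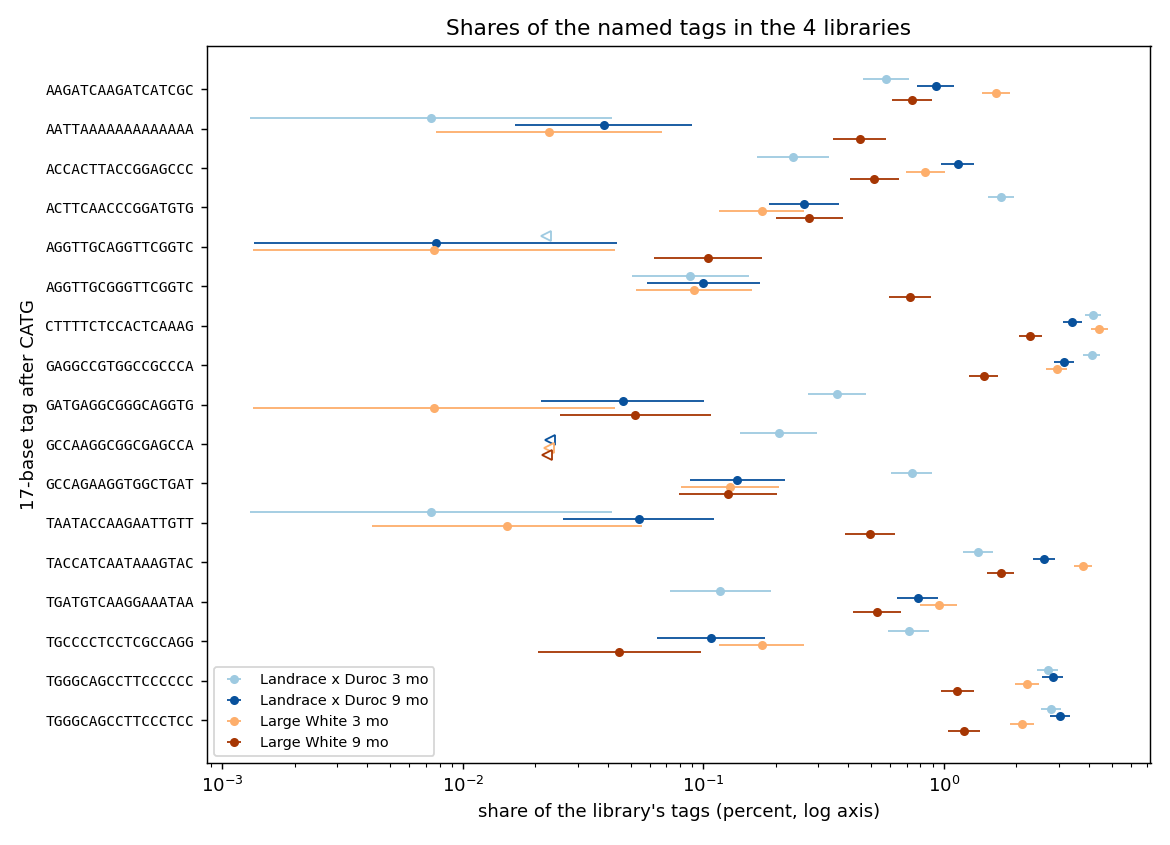
Share of each named tag (percent of the library's tags, log axis) in the 4 libraries, with 95% Wilson intervals that cover counting error only; open triangles mark the limit that a count of 0 allows. ACTTCAACCCGGATGTG lies highest in the Landrace x Duroc 3 month library, at 1.73%, and AGGTTGCGGGTTCGGTC highest in the Large White 9 month library, at 0.723%.

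The age change averaged over the pigs was tested with edgeR's quasi-likelihood test on the 4 libraries, with the pig as a block. A small p in this test does not require a change in each pig. CTTTTCTCCACTCAAAG and GAGGCCGTGGCCGCCCA were lower at 9 months in both pigs, with fitted log2 changes of -0.39 and -0.47, and neither passed after adjustment (adjusted p of 0.859 for both). GCCAAGGCGGCGAGCCA, the tag with the smallest unadjusted p among those that were lower, was seen 28 times in the Landrace x Duroc library at 3 months and 0 times in the other 3 libraries, so that its value rests on 1 pig. It was at least 8.91-fold lower at 9 months in that pig, taking a count of 0 at its limit of 3 counts per library, and did not pass over both pigs (adjusted p of 0.859). TAATACCAAGAATTGTT and AATTAAAAAAAAAAAAA had fitted log2 changes of 4.58 and 4.04 and the same adjusted p of 0.859. They went from 2 to 66 and from 3 to 60 tags in the Large White pig. In the Landrace x Duroc pig they went from 1 to 7 and from 1 to 5 tags, so a rise there rests on few tags. AGGTTGCAGGTTCGGTC, within 3 mismatches of AGGTTGCGGGTTCGGTC, had 0 and 1 tags in the Landrace x Duroc pig at 3 and 9 months and 1 and 14 in the Large White pig, again with an adjusted p of 0.859. No tag passed: edgeR called 0 of 464 tags, with 16 at an unadjusted p under 0.05, and DESeq2 also called 0, with 3 at an unadjusted p under 0.05. The fit had 1 residual degree of freedom and a common biological coefficient of variation of 0.475. On a single set of simulated libraries given that spread it recovered 0 of 81 tags changed 4-fold. Counting error entered these libraries again with the added spread, so they varied more than the fitted value implies. They do not settle whether changes of this size could be detected with 2 animals.

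The comparison of the lines at 3 months asked which transcripts differed between the fat and the lean animal at the younger age. ACTTCAACCCGGATGTG was 9.68-fold lower in the Large White library (6.34 to 14.8), with 23 tags against 235. GCCAGAAGGTGGCTGAT was 5.55-fold lower, with 17 tags against 100, and GATGAGGCGGGCAGGTG was seen 1 time against 49, a ratio of 31.9 with a counting interval of 6.28 to 162. TGATGTCAAGGAAATAA was 7.87-fold higher in the Large White library (4.71 to 13.1), with 125 tags against 16. TACCATCAATAAAGTAC was 2.72-fold higher, with 497 tags against 189, and AAGATCAAGATCATCGC was 2.85-fold higher, with 216 against 78. Adjusted p-values of these 6 tags by Fisher's exact test lay between 1.21e-41 and 7.79e-12. Of 464 tags, 77 passed, 38 higher and 39 lower in the Large White library. Tags that were higher in the Large White library had a median GC content of 41.2% and those that were lower 64.7%. Across the 464 tags, which are not independent replicates, Spearman's correlation between GC content and log2 difference was -0.34. Removing the GC trend left 60 tags, of which 47 were among the 77, and lowered the log2 difference of TACCATCAATAAAGTAC from 1.44 to 0.73 and that of TGATGTCAAGGAAATAA from 2.98 to 2.26.

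At 9 months the Large White library was again set against the Landrace x Duroc library. AGGTTGCGGGTTCGGTC was 6.99-fold higher in the Large White library (3.96 to 12.3), with 97 tags against 13. TAATACCAAGAATTGTT was 8.58-fold higher (4.03 to 18.2), with 66 tags against 7, and AATTAAAAAAAAAAAAA was 10.6-fold higher (4.45 to 25.5), with 60 against 5. All tags that end in 8 A together numbered 146 against 47. TGGGCAGCCTTCCCTCC, TGGGCAGCCTTCCCCCC and GAGGCCGTGGCCGCCCA were 2.50-fold, 2.48-fold and 2.15-fold lower, with 163, 153 and 197 tags against 395, 368 and 411. Adjusted p-values of these 6 tags by Fisher's exact test lay between 7.99e-23 and 3.42e-11. Of 464 tags, 68 passed, 21 higher and 47 lower in the Large White library, and the median log2 difference over all tags tested was -0.58. Under TMM scaling 33 passed, 26 higher and 7 lower, and with the GC trend removed 26 passed, 22 higher and 4 lower. With the GC trend removed the log2 differences of the 3 lower tags were -0.38, -0.37 and -0.16, and none of the 3 passed. All 3 still passed under TMM scaling. The GC setting also removes a shift of the whole library, so the smaller differences cannot be put down to GC content alone. Counting each repeated ditag a single time lowered the log2 differences of TAATACCAAGAATTGTT and AATTAAAAAAAAAAAAA to 1.82 and 2.19, the latter from 3.41.

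**Figure D3:**
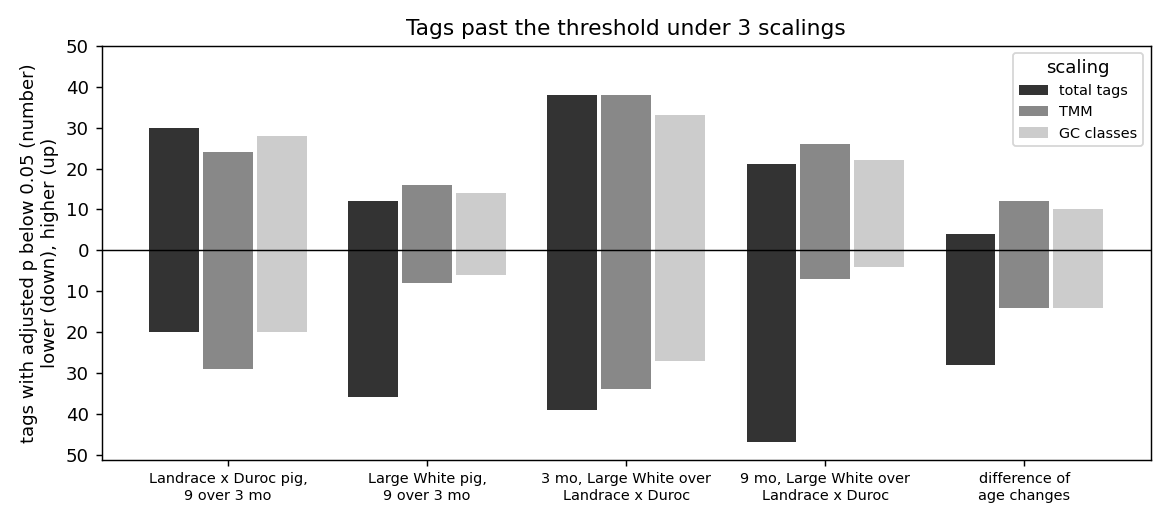
Number of tags with an adjusted p below 0.05 (bars up, higher; bars down, lower) in each comparison, with libraries scaled by their total tags, by TMM, or within 5 classes of GC content. In the comparison of the lines at 9 months 47 tags were lower with total tags and 7 with TMM, whereas the 3 month comparison gave 39 and 34.

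The age change itself was compared between the pigs with a z test of the difference of the log odds ratios. TACCATCAATAAAGTAC rose in the Landrace x Duroc pig and fell in the Large White pig, a log2 difference of -2.09 ± 0.18 (SE). ACCACTTACCGGAGCCC and TGATGTCAAGGAAATAA differed in the same direction, by -2.98 ± 0.36 and -3.55 ± 0.44. ACTTCAACCCGGATGTG and GCCAGAAGGTGGCTGAT fell in the Landrace x Duroc pig and differed by 3.37 ± 0.46 and 2.35 ± 0.61. AGGTTGCGGGTTCGGTC rose in the Large White pig, from 12 to 97 tags, against 12 and 13 tags in the Landrace x Duroc pig, a difference of 2.76 ± 0.71. Of 464 tags, 32 passed, 4 with a larger and 28 with a smaller log2 change in the Large White pig, and under TMM scaling 26 passed, 12 larger and 14 smaller. Counting each repeated ditag a single time left 21.

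Tags that rose with age in the Landrace x Duroc pig were compared with those that changed in the Large White pig. None of the 30 tags that rose in the first was among the 12 that rose in the second, where independent lists would share 0.776. In turn, 9 of the 30 were among the 36 that fell, against 2.33. Of the 20 that fell in the Landrace x Duroc pig, 4 also fell in the Large White pig, against 1.55. Under TMM scaling and with the GC trend removed, where 8 and 6 tags fell in the Large White pig in place of 36, the 9 became 2 and 2, against 0.414 and 0.362. The 4 became 3 and 1, against 0.5 and 0.259. The number for independent lists, here and below, takes every tag as equally likely to pass. Frequent tags pass more easily: in simulations 8 of 11 tags changed 2-fold and with 40 or more copies in the 2 libraries compared were recovered, against 10 of 83 among all. Lists can therefore share more than that number without related changes. Across the 464 tags the log2 age changes of the pigs had a Pearson correlation of -0.12, and 0.01 over the 108 tags with 40 or more copies over the 4 libraries. The line differences at the 2 ages, which also share no library, had a correlation of 0.16, and 0.29 over the 108 tags; with the GC trend removed these were 0.09 and 0.17. At both ages 2 tags were higher in the Large White library, against 1.72 for independent lists, and 7 were lower, against 3.95. Another 8 were higher at 3 months and lower at 9 months, against 3.85, and 0 were lower and then higher, against 1.77. Under TMM scaling the 7 became 2, against 0.513, and the 8 became 1, against 0.573. With the GC trend removed they became 1, against 0.233, and 2, against 0.284. The 30 tags that rose with age in the Landrace x Duroc pig shared 17 with the 38 that were higher in the Large White library at 3 months, against 2.46 for independent lists. Of the 20 that fell, 14 were among the 39 that were lower in the Large White library, against 1.68. Both of these comparisons used the Landrace x Duroc 3 month library, and part of the excess may come from it. Under TMM scaling the 17 became 16, against 1.97, and the 14 became 19, against 2.13. With the GC trend removed they became 16, against 1.99, and 10, against 1.16. Other comparisons that share a library also shared tags. The Large White age comparison and the lines at 9 months shared 11 higher and 20 lower tags, against 0.543 and 3.65 for independent lists; under TMM scaling they shared 13 higher and 1 lower, against 0.897 and 0.121, and with the GC trend removed 12 and 1, against 0.664 and 0.052. Of the 36 tags that fell with age in the Large White pig, 18 were higher in the Large White library at 3 months, against 2.95, and 13 of the 30 that rose in the Landrace x Duroc pig were lower in the Large White library at 9 months, against 3.04. Under TMM scaling the 18 became 5, against 0.655, and the 13 became 3, against 0.362. With the GC trend removed they became 4, against 0.427, and 3, against 0.241. The lists of lower tags in the Large White pig and at 9 months were shorter under these scalings, and the number that independent lists would share fell with them. For the pairs of comparisons with the Landrace x Duroc 3 month or the Large White 9 month library in common, 100 simulations of unchanged libraries gave 0 shared tags, but they leave out real deviations of the shared library and do not bear on their part in the excess. All p-values from a pair of libraries compare those libraries, not ages or lines, and have no replicate check.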

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

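The age change differed between the pigs, by the z test of the difference, for 32 tags. Among the named tags the log2 change of the Large White pig minus that of the Landrace x Duroc pig was 3.37 for ACTTCAACCCGGATGTG, 2.76 for AGGTTGCGGGTTCGGTC and 2.35 for GCCAGAAGGTGGCTGAT. It was -2.09 for TACCATCAATAAAGTAC, -2.98 for ACCACTTACCGGAGCCC and -3.55 for TGATGTCAAGGAAATAA. Each pig gave 1 library per age, so these differences separate 4 libraries and not the lines.

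The deposited lists of repeated ditags, which entered the comparisons only as an alternative count, held ditags well above the limit of a count of 0. Repeated ditags made up 15.1% of valid ditags in the Landrace x Duroc 3 month library, 19.5% in the Landrace x Duroc 9 month library, 15.4% in the Large White 3 month library and 6.94% in the Large White 9 month library. The most frequent pair in these lists joined CCTACTAAGCGGGGAGG and TACCATCAATAAAGTAC. It was seen 50, 100, 96 and 46 times in the same order of libraries, which is 10.8, 9.37, 9.39 and 13.2 times the number that random pairing of the tags gives.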

How the results depend on the processing

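Besides the overlaps and correlations under other scalings, 3 settings were chosen after the data were seen: tags shortened to 15 bases, the repeat-like family left out, and, for the age fit over both pigs, repeated ditags counted a single time. Counting repeated ditags a single time lowered the Landrace x Duroc age comparison from 50 to 31 tags and the difference of the age changes from 32 to 21; all of those 31 and 21 were among the original tags. TMM scaling lowered the Large White age comparison from 48 to 24 tags and the lines at 9 months from 68 to 33. Removing the GC trend lowered them to 20 and 26. These corrections bring the median log2 change of -0.50 and -0.58 to between 0.03 and 0.14, which removes tags that were lower and adds some that were higher. Both comparisons used the Large White 9 month library. Tags seen a single time made up 49.3% of it, against 25.8% to 32.5% of the other libraries, which left a smaller share for frequent tags. What caused this composition and the median shift was not tested. The other counts stayed within 1.5 times of the original, the line comparison at 3 months between 60 and 77 tags over all its alternatives. The age fit over both pigs called 0 tags under each setting, the fit without the pig block included, with 3 to 27 at an unadjusted p under 0.05.

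Of 267 values of single named tags under alternatives of the comparisons of 2 libraries and of the difference of the age changes, 0 changed sign, and 4, all with the GC trend removed, no longer passed. Outside the 95% interval of the reported value lay 29: 12 with repeated ditags counted a single time, 10 with the GC trend removed and 7 under TMM scaling. Each of the other settings put 0 values outside it. A different minimum of tags and the Audic-Claverie test leave the log2 value as it is, so their values could neither move nor change sign. The total of 267 therefore overstates how many values were put to a test. In the age fit over both pigs, where no tag passed, 9 of 152 values changed sign, and the cause was not tested. TACCATCAATAAAGTAC, at 0.11, went to -0.067 with a minimum of 5 tags, -0.12 without TMM and -0.088 without the pig block. AAGATCAAGATCATCGC, at -0.01, went to 0.025 with a minimum of 20 tags and 0.089 with repeated ditags counted a single time. TGGGCAGCCTTCCCCCC and TGGGCAGCCTTCCCTCC, at -0.22 and -0.11, went to 0.0076 and 0.12 with the GC trend removed and to 0.032 and 0.14 with repeated ditags counted a single time. Of 34 values of 1 pig alone, 8 had the opposite sign to the fit. Alternatives that need transcripts (other sites of a gene, mitochondrial tags left out, gene lists) were not run, and testing each tag by itself is the same as the tests reported. The age fit over both pigs pairs the ages within each animal. No paired analysis was possible because each group holds 1 library for the other comparisons. Depth limits the pairwise tests: among simulated tags with 40 or more copies in the 2 libraries compared, 8 of 11 changed 2-fold were recovered, against 10 of 83 among all.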

Other observations

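All tests in this part were chosen after the results they bear on had been seen, except the test for mixed material. Among tags of 8 or more copies, 14 pairs were examined that differ at 1 of the first 15 positions, counted from 1 at the first base after CATG, and the share of the forms differed between the pigs for 4 of them (Fisher's exact test with Benjamini-Hochberg adjustment). TCATCCGGCAAAATGCG differs from its partner by A11G and made up 29 of 29 and 37 of 37 tags of the pair in the Landrace x Duroc libraries at 3 and 9 months. In the Large White libraries it made up 1 of 23 and 6 of 28. The other pairs were AAGGCTCCACCGTCACT with A9G, GTAGGGGAAGGAGAAGG with A14G and CTGTCGGTGACATTCCT with C5T. A further pair, TGGGCAGCCTTCCCCCC with C15T, held both forms at shares of 48.2% to 51.2% for the first in every library.

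The 4 pairs were picked for a difference in shares and not for a change of the main form, and in 4 of them each form was the main form of at least 1 library. Over the 4 pairs the form that made up 0 of 76 and 0 of 61 tags in the Landrace x Duroc libraries made up 66 of 67 in the Large White 3 month library, which argues against sequencing errors of a single form. The main form changed with age within a pig 0 times, as a sequence variant that differs between the pigs would give. The pairs were picked for a difference between the pigs over both ages, which favours this outcome, so it lends little support. The form of the Landrace x Duroc pig made up 1 of 67 tags in the Large White 3 month library and 12 of 55 in the 9 month library (21.8%, 95% Wilson interval 12.9% to 34.4%). Fisher's two-sided exact test on the pooled tags gave p = 0.000512 and an exact test stratified by pair p = 0.00189. Unless material of the other pig was mixed in, this argues against a single animal homozygous at every one of these pairs behind both libraries. No pair passed by itself: the exact p was 0.112 for A11G, 1 for A9G, 0.222 for A14G and 0.0578 for C5T, and the A9G pair held 0 of 5 Landrace x Duroc forms at 9 months. Mixed material from the Landrace x Duroc 9 month library remains open. The test for it asked for tags with at least 15 copies in that library that were nearly lacking in the Large White 3 month library. It counted 0 tags, so its sum of 0 decides nothing. The Landrace x Duroc form of the first pair was not counted. That form had 37 copies in the Landrace x Duroc 9 month library. It had 1 and 6 in the Large White libraries at 3 and 9 months. A heterozygous animal with unequal use of its copies also stays open, untested, as does a different Large White animal at 9 months, which would go against the series' design text, on which the pig block of the age fit rests.

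The Large White 9 month library held 2424 more distinct tags than the Large White 3 month library. Copies of tags within 2 edits of abundant tags, scaled to the whole library, amount to 25.7% of this excess (15.8% to 35.7%), which argues against sequencing errors as the whole cause. This percentage sets copies against distinct tags. The near tags were 549 copies of 388 distinct tags at 3 months and 432 copies of 307 at 9 months. With each ditag counted a single time and every library thinned to 10450 tags, the library kept 1.31 times the distinct tags of the next library. This argues against fewer repeated ditags as the whole cause and leaves a part for them open. Tags within 3 mismatches of AGGTTGCGGGTTCGGTC made up 2.73% of it and 0.347% to 0.388% of the others, and the lowest of 4 such repeat-like groups was 2.33 times more frequent than in any other library. Genomic DNA or unspliced RNA that carries interspersed repeats is a candidate explanation that stays open, because the groups were picked after their counts were seen and they make up 9.03% of the excess. A single transcript read with errors is argued against for the first group: it held 277 near tags per 100 copies of AGGTTGCGGGTTCGGTC, against at most 73.3 for 28 other tags with 40 or more copies, and AGGTTGCGGGTTCGATC alone reached 24.7% of it, against at most 6.67%. By the number of different 1-base variants, 17.5 per 100 copies, it lay above 9 of 10 comparison tags and below TAATACCAAGAATTGTT at 18.2.

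The mean GC content of the tags was 6.19 percentage points higher in the Landrace x Duroc than in the Large White library at 3 months and 6.07 points higher at 9 months. Without the 20 most abundant tags at least 96.7% of the difference was kept at each age, which argues against a few abundant tags as its cause. Scaling within 5 GC classes left 47 of the 77 line differences at 3 months, so shifts between these classes do not account for all of the calls. The scaling applies a single factor to each class of tag GC content and cannot remove loss that varies within a class. GC-dependent loss in library making therefore stays open for the 47 as for the other 30. A biological difference between the lines also stays open and was not tested.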
